A study of Mus musculus with 8 samples.

How the data were processed

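MicroRNAs (miRNAs) were measured in livers of male C57BL/6 mice on 8 single-colour Agilent arrays. Per the labels, 3 arrays came from mice with a ligated bile duct (BDL), 3 from LIX1L knockout mice with a ligated duct (LIX1L KO BDL) and 2 from sham-operated mice, and each array was a biological replicate. All 8 arrays lay on 1 slide and were scanned in 1 session, so slide and scan could not differ between groups. BDL arrays and LIX1L KO BDL replicate 2 lay in row 1 of the slide, and the remaining arrays in row 2. The rows differed in array quality. The scanner software found 46.1% to 51.9% of miRNA spots in row 1 and 58.8% to 73.2% in row 2. It marked 2.66% to 2.68% as population outliers in row 1 and 1.86% to 2.17% in row 2. The lowest scaled signal well above background was 11.0 to 12.3 in row 1 and 13.6 to 18.2 in row 2. BDL against sham was thus also row 1 against row 2.

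Per the file headers, the authors read the spots with Agilent Feature Extraction 10.7.1.1, with spatial detrending on and local background correction off. The deposited spot values are intensity (processed signal after subtraction of a fitted spatial surface), with no scaling between arrays per the file headers. The deposited table of all spots held the same intensity values as the scanner files, spot by spot. A further deposited table, whose name refers to quantile, held log2 values per miRNA, and its normalization is not given in the sources used here. Probe positions in the files refer to the mouse build mm9.

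Each array carried 58594 miRNA spots, with 7 to 30 spots per probe, for 4415 probes and 1881 miRNAs with up to 4 probes each. Control spots and spots marked as outliers by the scanner software were left out, and the remaining spots of a probe were averaged. Under 1 in 10 probes, 279 of 4415 (6.32%), were well above background on all 8 arrays. Each array was divided by its 75th percentile over those 279 probes and multiplied by the mean percentile. Signals were then floored at 13.0, the median over arrays of the lowest scaled signal of a probe well above background, which is 3.70 on the log2 scale, and log2 was taken. A miRNA was read from its probe with the highest mean over all arrays. The files marked no spot as saturated (0 spots). The number of arrays limits the precision: the median standard error of a log2 difference was 0.174 for BDL against sham and 0.156 for LIX1L KO BDL against BDL.

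A miRNA was tested where most spots of at least 1 of its probes were well above background on every array of at least 1 group, which left 219 miRNAs. The 3 groups were fitted together with limma 3.58.1 (lmFit and eBayes, R 4.3.3), with 5 residual and 2.76 prior degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment over the 219 miRNAs within a comparison, and a miRNA was called at an adjusted p under 0.05. The pooled spread let the pair of sham arrays enter a test. Where a miRNA was well above background on no array of the dimmer group, the text gives a lower bound on the fold: the mean of the brighter group against the mean, over the dimmer arrays, of the higher of the lowest signal well above background and the probe's own signal. Files were read with jsonlite 2.0.0 and the R package data.table, version 1.17.8.

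The comparisons were BDL against sham, LIX1L KO BDL against BDL and, as a secondary one, LIX1L KO BDL against sham. No sham-operated knockout group was among the samples, so an interaction of knockout and ligation could not be fitted. LIX1L messenger RNA is outside what a miRNA array measures, so the knockout could not be checked here. The test, the samples in the fit, the named miRNAs, the lists and most alternatives were fixed before the data were examined. Named miRNAs were, in the first and the second comparison, the 10 largest rises and the 10 largest falls among called miRNAs whose arrays did not overlap between groups. Where fewer than 5 passed in a direction, the 5 with the smallest unadjusted p were taken. From each list up to 3 tested members with the smallest p were added, as were miR-122-5p, miR-21a-5p, miR-34a-5p, miR-191-5p and miR-191-3p, and the 5 largest per direction in the last comparison.

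The 21 lists covered hepatocyte-abundant miRNAs, other cell types (stromal and stellate, biliary and other epithelial, leukocyte and macrophage, endothelial, erythroid, muscle, pancreas, neural), miRNAs reported as raised in fibrosis or linked to bile acids and nuclear receptors, and families or clusters (miR-29, miR-30, let-7, miR-17-92, miR-15/16, miR-23-27-24, miR-34, the miR-191 and miR-425 cluster, H19 and Igf2 hosted, Dlk1-Dio3). Some miRNAs stand on more than 1 list, and liver expresses miRNAs of most of them. Lists with at least 3 tested members, 12 in all, were tested with limma camera at its preset correlation of 0.01, with Benjamini-Hochberg over lists. The same test with an estimated correlation, and fry, were alternatives.

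The scripts were tested on 20 simulated sets of 219 miRNAs with the spread of these arrays. In sets simulated for BDL against sham, 44.8% of miRNAs changed by 0.5 log2 units were called, 83.2% of those changed by 1 and 99.0% of those changed by 2, and 1.16% of the unchanged ones were called. For LIX1L KO BDL against BDL the shares were 56.0%, 86.8% and 99.5%, with 0.975% of unchanged miRNAs called. For LIX1L KO BDL against sham they were 44.0%, 86.8% and 98.2%, with 1.45% of unchanged miRNAs called. A list shifted by 0.7 log2 units was called by camera in 19, 20 and 20 of 20 sets in the 3 comparisons, and in 17, 19 and 14 sets with an estimated correlation. The simulated miRNAs were drawn independently, with the smallest spreads raised. In the real arrays the estimated correlation within a list was, for example, 0.691 (hepatocyte-abundant) and 0.902 (stromal and stellate cell). The simulated list results therefore do not carry over to lists whose members move together.

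Alternatives fixed in advance were other scalings (75th percentile over all probes, quantile normalization, none), normexp background correction with an offset of 50, the mean of a miRNA's probes or the scanner software's total gene signal, other detection filters, a floor of 1, other models and thresholds, a block on the replicate number and each array left out in turn. Chosen after seeing the data were slide row as a block, a fit to 1 slide row, scaling by 8 spike-in probes and a correction for probe GC content. A slide or scan block was not run, with 1 slide and 1 scan.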

Results

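Liver miRNAs were profiled in mice with cholestasis and in normal mice. Bile duct ligation blocks the outflow of bile and leads to cholestatic liver injury, and LIX1L is a putative RNA-binding protein. There were 3 BDL mice (replicates 1, 3 and 4), 3 LIX1L KO BDL mice (replicates 2, 3 and 5) and 2 sham-operated mice (replicates 1 and 2). By the scanner software's flag, 303 to 324 miRNAs were detected on single arrays in BDL, 271 to 289 in LIX1L KO BDL and 277 to 291 in sham. Of the 1881 miRNAs on the array, 219 were tested. Levels below are log2 of the scaled, floored signal, as mean ± SD, with n arrays. Between arrays of 1 group the correlation across miRNAs was 0.995 for BDL replicates 1 and 3, and 0.990 for the sham pair. BDL replicate 4 correlated at 0.981 and 0.987 with BDL replicates 1 and 3, and at 0.988 to 0.991 with the LIX1L KO BDL arrays; these correlations run across miRNAs, which are not independent replicates.

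BDL against sham asked which liver miRNAs differ in cholestasis. MiR-21a-5p, a miRNA raised in many forms of tissue injury and fibrosis, rose 2.42-fold, from 12.39 ± 0.37 (SD, n = 2) in sham to 13.67 ± 0.16 (SD, n = 3) in BDL, but under quantile normalization its log2 change was 0.20 and not called. MiR-223-3p, which is abundant in neutrophils and other myeloid cells, rose 2.60-fold, from 6.98 ± 0.15 (n = 2) to 8.36 ± 0.38 (n = 3). Relative to the typical measured miRNA, miR-31-5p, both miR-19 members of the proliferation-linked miR-17-92 clusters, most of the miR-30 family and the hepatocyte miRNAs miR-192-5p, miR-194-5p, miR-148a-3p and miR-378a-3p fell. Of these 4 hepatocyte miRNAs only miR-378a-3p was also called under other scalings, 3 of 4. MiR-122-5p, the dominant miRNA of hepatocytes, had a level of 15.10 ± 0.13 (n = 3) in BDL and 15.51 ± 0.13 (n = 2) in sham, a change of −0.41 that did not pass (limma with Benjamini-Hochberg, adjusted p = 0.0742) and was 0.14 under quantile normalization.

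In all, 54 of 219 miRNAs were called, 22 higher and 32 lower in BDL (limma with Benjamini-Hochberg), and 91 had an unadjusted p under 0.05. At least 2-fold changes were called for 13 miRNAs higher and 3 lower in BDL. The arrays of the groups did not overlap for 134 miRNAs (61.2%), where chance gives 20%, and for all 54 called ones. Here and below, that chance share leaves out that the filter used the groups. It also leaves out that miRNAs on an array move together, so an excess over it is not a test. For 8 of the 54 only a lower bound on the fold could be given.

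The largest rises were in less studied miRNAs. MiR-5128 was well above background in 0 of 2 sham and 3 of 3 BDL arrays, and was at least 5.07-fold higher in BDL (limma with Benjamini-Hochberg, adjusted p = 0.0169). By the same test miR-125a-3p was at least 3.89-fold higher (adjusted p = 0.0115), miR-721 at least 2.74-fold (adjusted p = 0.00349) and miR-3472 at least 2.55-fold (adjusted p = 0.0319). MiR-3473b rose by 1.92 log2 units (SE 0.30, limma with Benjamini-Hochberg, adjusted p = 0.00397), miR-3470a by 2.05, miR-3473a by 1.66 and miR-7118-5p by 1.23. Calls were lost in 8 of 26 alternatives for miR-5128 (0.80 to 3.35), 10 for miR-3472 (0.38 to 3.66), 10 for miR-3473a (0.43 to 2.79), 5 for miR-125a-3p (0.52 to 2.46) and 1 for miR-721 (0.36 to 3.65), and in 6 of 27 for miR-7118-5p (0.43 to 1.61). The log2 rise was 1.38 (SE 0.22, adjusted p = 0.00397) for miR-223-3p and 1.27 (SE 0.17, adjusted p = 0.00354) for miR-21a-5p, by limma with Benjamini-Hochberg. The miR-21a-5p probe maps to chromosome 11, positions 86397588 to 86397607 (mm9), and the miR-223-3p probe to chromosome X, positions 93438225 to 93438244.

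The largest fall was that of miR-31-5p, from 6.30 ± 0.29 (n = 2) to 5.00 ± 0.17 (n = 3), a log2 change of −1.30 (SE 0.16, limma with Benjamini-Hochberg, adjusted p = 0.00349). Its probe maps to chromosome 4, positions 88556494 to 88556509 (mm9). MiR-19a-3p (−1.20) and miR-19b-3p (−1.10) followed, and the miR-19b-3p probe matches 2 loci, on chromosomes 14 and X. Further large falls were miR-378a-3p (−0.98), miR-652-5p (−0.97), miR-6366 (−0.96), miR-30e-5p (−0.91), miR-378b (−0.90), miR-92a-3p (−0.84) and miR-378d (−0.83). The call of miR-652-5p was lost in 11 of 27 alternatives (−1.34 to −0.55). Near-identical relatives (miR-378a-3p, b and d, miR-19a-3p and b, or miR-3473a and b) can cross-hybridise, so their values are not separate measurements. The probe of miR-5128 shares part of its sequence with those of miR-3473a and miR-3473b, so their rises may not be separate measurements either. Where a called miRNA had another measured probe, for 45 miRNAs, the other probe gave the opposite sign for 0, but for 7 of them less than 0.5 times the log2 change. Other probes of miR-125a-3p gave 0.24, 0.46 and 0.54, that of miR-19a-3p −0.39 and that of miR-7118-5p 0.27. The other probe of miR-5128, well above background on 1 of 8 arrays, and that of miR-3473a, on 0 of 8, were too dim to compare. The same holds for the other probe of miR-5112, on 1 of 8, and for 1 of those of miR-671-5p, on 2 of 8. Measured probes with no difference, as for miR-5128, miR-5112 and miR-671-5p, were counted above as not opposite in sign.

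**Figure D1:**
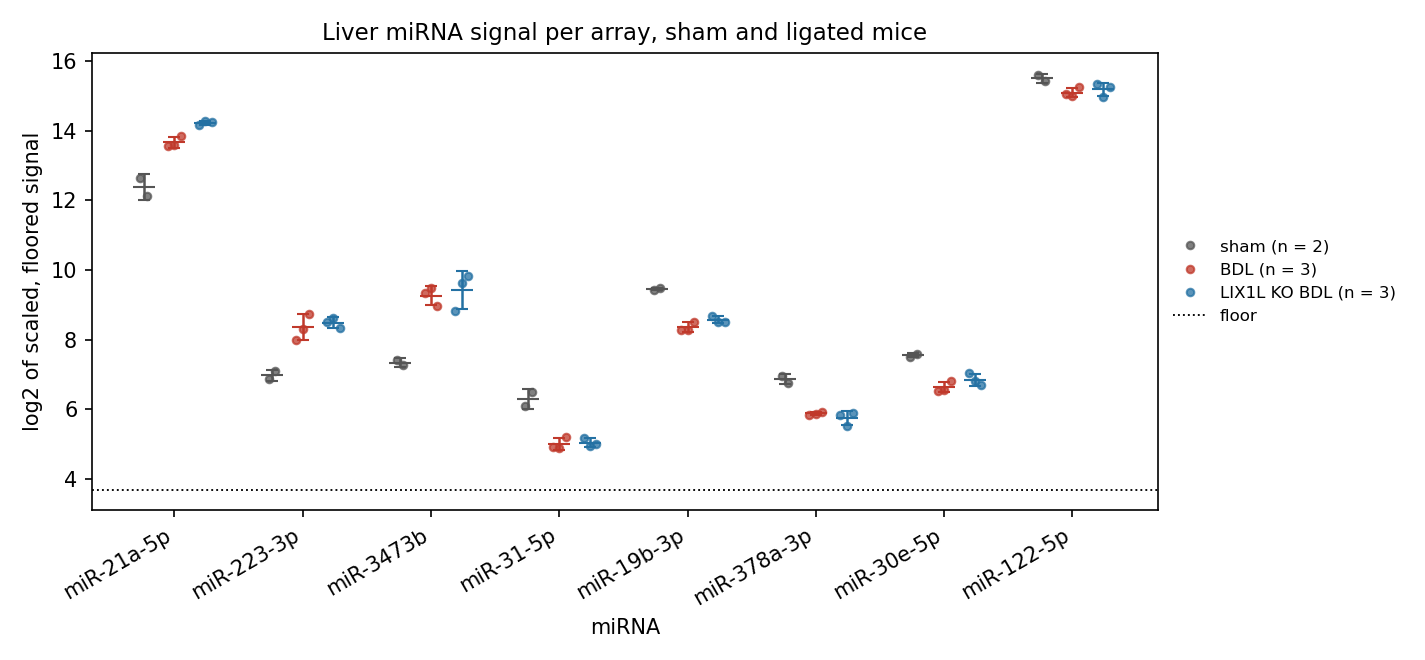
Level of 8 named miRNAs (x axis) as log2 of the scaled, floored signal (y axis) in sham, BDL and LIX1L KO BDL livers; dots are arrays, horizontal marks are means, bars are SD and the dotted line is the floor. MiR-21a-5p, miR-223-3p and miR-3473b lay higher in BDL than in sham on every array and miR-31-5p, miR-19b-3p, miR-378a-3p and miR-30e-5p lower, with the direction kept under each of the other 4 scalings.

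Of the lists, the hepatocyte-abundant miRNAs fell as a group: of 8 tested members 0 rose and 5 fell (0 and 7 adjusted over the list alone), with a median log2 change of −0.56. MiR-378a-3p changed by −0.98, miR-148a-3p by −0.63, miR-194-5p by −0.63 and miR-192-5p by −0.58; under the other 4 scalings the last 3 were never called and went down in size to −0.29, −0.25 and −0.13. Limma camera with Benjamini-Hochberg gave an adjusted p = 0.00411 for this list, and adjusted p = 0.832 with an estimated correlation; under quantile normalization camera gave 0.344. The miR-30 family, which is enriched in differentiated epithelial cells, had 0 rises and 7 falls among 8 tested members (0 and 7 adjusted over the list alone), with a median of −0.58. MiR-30c-5p changed by −0.68 and miR-30a-5p by −0.70. Of the other 4 scalings miR-30c-5p and miR-30b-5p were called under none (miR-30c-5p at −0.41 to −0.23), and the other 5 falls of the family only with quantile normalization. The camera test with Benjamini-Hochberg in limma gave this family an adjusted p = 0.00114, and adjusted p = 0.319 with an estimated correlation. The miR-17-92 and paralogous clusters, which are driven by MYC and promote proliferation, had 0 rises and 6 falls among 9 tested members (0 and 7 adjusted over the list alone), with a median of −0.70. MiR-20a-5p changed by −0.77 and was called only with quantile normalization among the other scalings. Limma camera with Benjamini-Hochberg gave these clusters an adjusted p = 0.00114, and adjusted p = 0.248 with an estimated correlation. The medians of these 3 lists stayed below 0 under every scaling tried, but with spike-in scaling they were −0.22 (hepatocyte-abundant, with 1 of 8 members called), −0.24 (miR-30 family) and −0.36 (miR-17-92 and paralogous clusters), and fry called the same number of lists, 3.

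Markers of other liver cell types went different ways. Of 5 leukocyte and macrophage miRNAs, 2 rose and 1 fell (2 and 2 adjusted over the list alone): miR-223-3p and miR-342-3p (0.45) were higher, and miR-511-3p (−0.45), which lies within a macrophage receptor gene, was lower. The call of miR-511-3p was lost in 20 of 27 alternatives, with its change down in size to −0.11, and that of miR-342-3p in 12 of 27, down to 0.26. This list's median was −0.18, its mean 0.14, and the median was above 0 without scaling, with spike-in scaling and with the percentile over all probes. Both tested endothelial miRNAs fell (0 rises and 2 falls also adjusted over the list alone): miR-126a-3p by −0.65, and miR-126a-5p, well above background on 1 of 3 BDL arrays, to the floor, so that the size of its fall is open. Under the other 4 scalings miR-126a-3p was never called, at −0.38 to −0.22, and miR-126a-5p only with quantile normalization. The erythroid miRNAs miR-451a (−0.90) and miR-486a-5p (−0.83) were not called, 0 of 2 (0 rises and 1 fall adjusted over the list alone). Of 7 stromal and stellate cell miRNAs 0 were called by limma (0 adjusted over the list alone), with a median of 0.27; miR-100-5p (−0.63), miR-143-3p (−0.52) and miR-214-3p (0.62) went both ways. Of 6 biliary and other epithelial miRNAs 0 rose and 2 fell (0 and 2 adjusted over the list alone), miR-31-5p and miR-203-3p (−0.63). The list's median was nevertheless 0.48, and its highest member, also not called, was at 1.48. MiR-96-5p, well above background on 0 of 2 sham arrays, was not called. Lists for muscle, pancreas and neural tissue had 0 tested members.

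Of 9 tested miRNAs reported as raised in fibrosis, 1 rose and 1 fell (1 and 1 adjusted over the list alone), miR-21a-5p and, against the list's name, miR-31-5p. Their median was 0.39 (limma camera with Benjamini-Hochberg, adjusted p = 0.315). MiR-34a-5p, a p53 target that represses SIRT1, was at 0.59 and was not called (limma with Benjamini-Hochberg, adjusted p = 0.0865; 1 rise of 1 adjusted over the list of its family alone). In the miR-29 family, which represses collagen genes, miR-29b-3p rose by 0.78, and 1 of 3 was called (1 adjusted over the list alone); miR-29c-3p was at −0.09 and miR-29a-3p at −0.03. The call of miR-29b-3p was lost in 11 of 27 alternatives, with changes of 0.41 to 1.16. That family's median was −0.03 and its mean 0.22, with the median above 0 under each of the other 4 scalings. Of 7 miRNAs linked to bile acids and nuclear receptors, 1 rose and 2 fell (2 and 3 adjusted over the list alone): miR-21a-5p was higher and miR-192-5p and miR-194-5p lower. Their median was −0.41, and 0.08 under quantile normalization.

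No member of the let-7 family (9 tested), the miR-15/16 family with miR-322 and miR-503 (6) or the miR-23-27-24 clusters (5) was called by limma, 0 in each (0 adjusted over each list alone). Members were let-7d-5p (−0.32), let-7g-5p (−0.37), let-7a-5p (−0.19), miR-15b-5p (−0.27), miR-322-5p (0.28), miR-16-5p (−0.13), miR-27a-3p (0.67), miR-23a-3p (0.44) and miR-23b-3p (−0.21). MiR-27a-3p was called in 14 of 27 alternatives (0.54 to 1.01) and let-7d-5p in 6 of 27. The let-7 median was −0.19 but above 0 under each of the other 4 scalings, and the miR-15/16 median of −0.13 was above 0 under 3 of them; the miR-23-27-24 median was 0.04. MiR-425-5p (0.06) and miR-494-3p (0.26) were the only tested members of the miR-191 and miR-425 cluster and of the Dlk1-Dio3 cluster, and 0 of the H19 and Igf2 hosted miRNAs were tested. MiR-191-5p and miR-191-3p were well above background on 0 of 8 arrays; by the scanner software's detection flag miR-191-3p was detected on 8, with a BDL against sham change of −0.02 and values at the floor on 6 arrays.

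The balance of rises and falls depended on the scaling. The 75th percentile of the detected probes was 1.21 times as high in BDL as in sham, where the spike-in probes had a ratio of 0.953, so changes here are relative to the measured miRNAs. Against this scaling the median change shifted by 0.33 with the percentile over all probes (43 higher and 1 lower called), 0.27 without scaling (47 and 7) and 0.34 with spike-in scaling (64 and 9); it shifted by −0.04 with quantile normalization (22 and 24). All 54 called miRNAs kept their sign under these 4 scalings; 19 of the 22 rises and 1 of the 32 falls, miR-31-5p, were called under every one, and miR-21a-5p was not called under quantile normalization (0.20). Total gene signal gave 22 higher and 18 lower, and the floor of 1 gave 31 and 30. Slide row and group cannot be told apart in this comparison, since all BDL arrays lay in row 1 and both sham arrays in row 2. A block on slide row takes its row effect from the knockout arrays alone, replicate 2 in row 1 against replicates 3 and 5 in row 2. With that borrowed row effect 25 were higher and 21 lower, and all 54 kept their sign and 31 their call (11 rises and 20 falls). The list medians were then −0.90 (hepatocyte-abundant), −0.71 (miR-30 family) and −0.59 (miR-17-92 and paralogous clusters). The count was 84 without BDL replicate 4, 35 without BDL replicate 1, 31 without BDL replicate 3 and 28 (6 higher and 22 lower) without sham replicate 2, and 9 were higher and 37 lower without sham replicate 1.

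**Figure D2:**
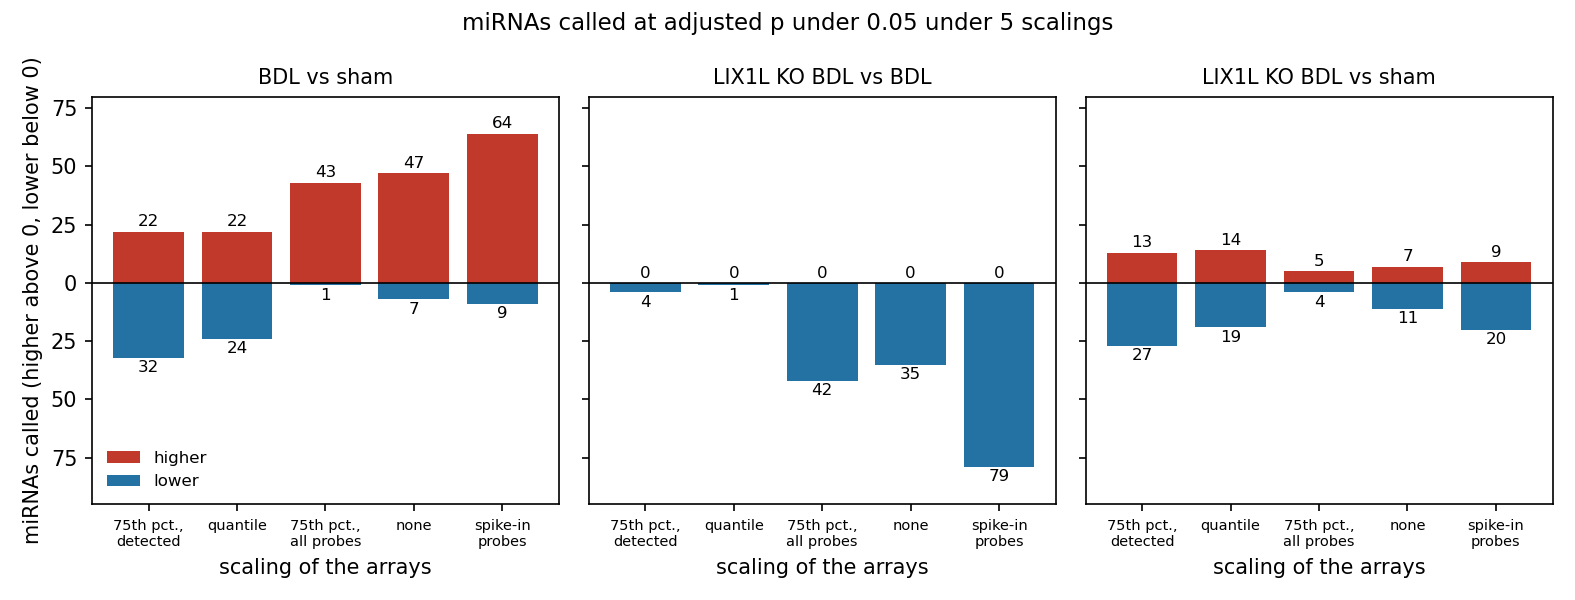
Number of miRNAs called higher (above 0) and lower (below 0) in each comparison (panels) under 5 scalings of the arrays (x axis). In BDL against sham the split went from 22 higher and 32 lower with the percentile of detected probes to 64 and 9 with spike-in scaling, and in LIX1L KO BDL against BDL from 4 lower to 79 lower.

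LIX1L KO BDL against BDL asked which miRNAs depend on LIX1L in ligated mice. Only 4 of 219 miRNAs were called, all lower in the knockout. MiR-146a-5p, which is induced by NF-kappaB and represses IRAK1 and TRAF6, fell 1.79-fold, from 4.93 ± 0.29 (SD, n = 3) in BDL to 4.09 ± 0.12 (SD, n = 3) in the knockout, where it was well above background on 1 of 3 arrays. Its call was lost in 19 of 27 alternatives, and its log2 change ran from −1.17 to −0.083, the latter with normexp background. MiR-721, among the largest rises after ligation, was near the floor in the knockout, at 3.82 ± 0.22 (n = 3) against 5.23 ± 0.30 (n = 3), with 1 of 3 knockout arrays well above background. MiR-721, miR-6898-5p and miR-3963 were called higher in BDL than in sham, and both comparisons use the same BDL arrays. High values on those arrays alone would give a rise and then a fall, so a reversal cannot be read from them. MiR-146a-5p was at −0.49 in BDL against sham and was not called. MiR-21a-5p stood at 14.23 ± 0.06 (n = 3) against 13.67 ± 0.16 (n = 3) and did not pass.

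The log2 changes were −1.41 for miR-721 (SE 0.18, limma with Benjamini-Hochberg, adjusted p = 0.0116), −1.18 for miR-6898-5p (SE 0.22), −0.84 for miR-146a-5p (SE 0.16) and −0.73 for miR-3963 (SE 0.14). The last 3 had an adjusted p = 0.0446 by limma with Benjamini-Hochberg, and each of the 4 was lower in 3 of 3 knockout arrays than in any BDL array. Calls were lost in 12 of 27 alternatives for miR-721, whose change ran from −2.77 to −0.34, in 19 of 28 for miR-6898-5p (−1.51 to −0.35) and in 18 of 28 for miR-3963 (−1.07 to −0.60). The miR-146a-5p probe maps to chromosome 11, positions 43187908 to 43187925 (mm9), and no position was used here for the other 3. MiR-125a-3p was at −1.88 and did not pass (limma with Benjamini-Hochberg, adjusted p = 0.0509), but was called in 8 of 27 alternatives (−2.37 to −0.53). Of rises 0 were called by limma: the smallest p values were those of miR-185-5p (0.51), miR-21a-3p (0.61), miR-21a-5p (0.57), miR-19a-3p (0.45) and miR-345-5p (0.39), with adjusted p values of 0.0642 to 0.0924 by limma with Benjamini-Hochberg. At an unadjusted p under 0.05 there were 38 miRNAs, and the groups did not overlap for 49 (22.4%), where chance gives 10%.

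**Figure D3:**
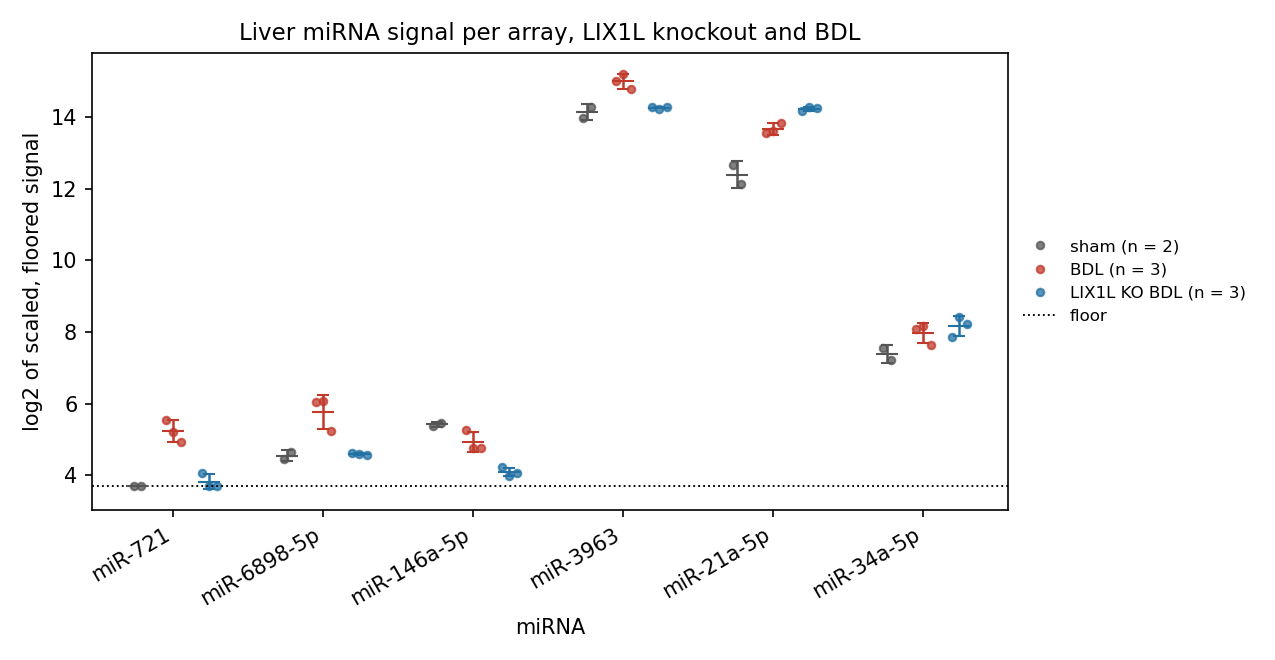
Level of the 4 called miRNAs and of miR-21a-5p and miR-34a-5p (x axis) as log2 of the scaled, floored signal (y axis) in sham, BDL and LIX1L KO BDL livers; dots are arrays, horizontal marks are means, bars are SD and the dotted line is the floor. MiR-721 lay at 4.93 to 5.54 on the BDL arrays and at 3.70 to 4.07 on the knockout arrays, and the 4 falls kept their direction under each of the other 4 scalings.

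Of the miRNAs reported as raised in fibrosis, 9 were tested and 0 called (2 rises adjusted over the list alone), but the list was shifted upwards, with a median of 0.38. Limma camera with Benjamini-Hochberg gave an adjusted p = 0.0439, and adjusted p = 0.654 with an estimated correlation. Its members included miR-21a-3p, miR-21a-5p, miR-199b-5p (0.66), miR-214-3p (0.57), miR-199a-3p (0.38) and miR-34a-5p (0.20). Without LIX1L KO BDL replicate 3 the median of fibrosis-raised in the literature was 0.069, miR-199b-5p was at 0.20, miR-214-3p at 0.18 and miR-199a-3p at −0.023. Limma camera called 0 lists without that array, and also without BDL replicate 1, BDL replicate 4, LIX1L KO BDL replicate 2 or either sham array. The miR-23-27-24 clusters had 0 called of 5 (0 adjusted over the list alone) and a median of 0.25, which was −0.08 with the percentile over all probes, −0.05 without scaling and −0.08 with spike-in scaling in the miR-23-27-24 clusters. Limma camera with Benjamini-Hochberg gave an adjusted p = 0.0439 here too, and adjusted p = 0.654 with an estimated correlation. Members were miR-27b-3p (0.25), miR-23b-3p (0.24) and miR-24-3p (0.26). With slide row as a block neither list was called by limma camera. In that fit the knockout side rests on LIX1L KO BDL replicate 2 alone. On that 1 array the median was 0.29 for the hepatocyte-abundant list and 0.28 for the bile acid and nuclear receptor linked list. Fry called 0 lists in this comparison.

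Other lists had 0 calls by limma, apart from the fall of miR-146a-5p among 5 leukocyte and macrophage miRNAs (0 rises and 1 fall adjusted over the list alone). Hepatocyte-abundant miRNAs (8 tested) had a median of 0.06, below 0 with spike-in scaling, without scaling and with the percentile over all probes, with miR-22-3p at 0.27, miR-101a-3p at 0.34, miR-122-5p at 0.10 and miR-378a-3p at −0.12. Stromal and stellate miRNAs (7) had a median of 0.36, which kept its sign under the other scalings but was −0.047 without LIX1L KO BDL replicate 3 (stromal and stellate cell). The medians were 0.08 for the miR-30 family (8), 0.06 for the let-7 family (9), 0.09 for the miR-17-92 and paralogous clusters (9) and 0.08 for the miR-15/16 family (6), each below 0 under the same 3 scalings and that of let-7 under quantile normalization too. Biliary and other epithelial miRNAs (6) had a median of 0.21, below 0 under the same 3 scalings, with miR-183-5p at 0.64 and miR-96-5p at 0.68 (2 rises adjusted over the list alone). The bile acid and nuclear receptor list (7) had a median of 0.20, below 0 under the same 3 scalings, with miR-210-3p at 0.41 (1 rise adjusted over the list alone). The remaining members named by the rule were not called either: miR-29b-3p was at 0.22, miR-29c-3p −0.14, miR-30d-5p 0.28, miR-30e-5p 0.22, miR-30c-5p 0.10, let-7e-5p 0.36, miR-98-5p 0.14, let-7c-5p −0.15, miR-203-3p −0.13, miR-342-3p −0.13, miR-223-3p 0.13, miR-126a-5p 0.10, miR-126a-3p 0.01, miR-451a 0.20, miR-486a-5p 0.07, miR-19b-3p 0.22, miR-18a-5p 0.15, miR-322-5p 0.20, miR-16-5p −0.08, miR-15a-5p 0.08, miR-425-5p 0.07 and miR-494-3p −0.34, and 0 of the lists outside those named before had a call adjusted over the list alone.

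The number of calls in this comparison depended on scaling and on single arrays. The 75th percentile of detected probes was 0.812 times that of BDL in the knockout, against a spike-in ratio of 1.02, and the median change shifted by −0.33 with the percentile over all probes (42 lower), −0.30 without scaling (35 lower), −0.33 with spike-in scaling (79 lower), −0.11 with total gene signal (1 higher, 2 lower) and 0.05 with quantile normalization (1 lower), with 0 higher unless given. Of the 4 falls, miR-721 was called under the other 4 scalings of the spot signal, and 0 of the 4 with total gene signal. With slide row as a block 0 were called by limma (50 at an unadjusted p under 0.05), and the 4 changes were −0.71 to −1.16. Within row 1, which held the BDL arrays and 1 knockout array, the 4 changes were −0.73 to −1.19. Both fits set LIX1L KO BDL replicate 2 alone against the BDL arrays, so they are not separate checks. Without BDL replicate 4 there were 29 calls (6 higher, 23 lower); without BDL replicate 1, LIX1L KO BDL replicate 2 or LIX1L KO BDL replicate 3 there was 1 each, and without BDL replicate 3, LIX1L KO BDL replicate 5, sham replicate 1 or sham replicate 2 limma called 0, with 28 to 44 at an unadjusted p under 0.05. After the correction for probe GC content 1 was called, miR-721.

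LIX1L KO BDL against sham combined genotype and operation. MiR-21a-5p was 3.58-fold higher in ligated knockout mice, miR-3473b 4.25-fold and miR-223-3p 2.85-fold, while miR-146a-5p, miR-31-5p and miR-378a-3p were lower. Under quantile normalization miR-21a-5p was at a log2 change of 0.96 and not called. In all 40 of 219 miRNAs were called, 13 higher and 27 lower (limma with Benjamini-Hochberg), 65 had an unadjusted p under 0.05, and the groups did not overlap for 101 (46.1%), where chance gives 20%. The largest rises were those of miR-3473b (2.09, SE 0.30), miR-21a-5p (1.84, SE 0.17), miR-3473a (1.77), miR-223-3p (1.51) and miR-96-5p, which was at least 2.41-fold higher than in sham, where it was well above background on 0 of 2 arrays. The largest falls were miR-146a-5p (−1.33, SE 0.17), miR-31-5p (−1.26), miR-677-3p (−1.22), miR-378a-3p (−1.11) and miR-378b (−0.95). Adjusted p values of these 10 ran from 0.00155 for miR-21a-5p to 0.0178 for miR-3473a (limma with Benjamini-Hochberg). Calls were lost in 8 of 27 alternatives for miR-3473a (0.59 to 2.17) and in 5 of 27 for miR-96-5p (0.41 to 1.72), and in at most 3 for each other of these 10. MiR-34a-5p was called here, 0.78 higher (limma with Benjamini-Hochberg, adjusted p = 0.0470), and under 2 of the other 4 scalings.

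By list, 3 of 9 fibrosis-raised miRNAs rose (miR-21a-5p, miR-21a-3p, at least 1.73-fold, and miR-34a-5p) and miR-31-5p fell, with a median of 0.78 (3 and 1 adjusted over the list alone); limma camera with Benjamini-Hochberg gave an adjusted p = 0.00380, and adjusted p = 0.396 with an estimated correlation. Among hepatocyte-abundant miRNAs 0 rose and 3 fell (0 and 5 adjusted over the list alone), with a median of −0.50 and, by the same camera test in limma with Benjamini-Hochberg, an adjusted p = 0.0161, and adjusted p = 0.679 with an estimated correlation; under quantile normalization camera gave 0.184 for hepatocyte-abundant miRNAs. In the miR-30 family 0 rose and 6 fell (0 and 7 adjusted over the list alone), with a median of −0.56, and in the miR-17-92 and paralogous clusters 0 rose and 5 fell (0 and 5 adjusted over the list alone), with a median of −0.75. Both had an adjusted p = 0.00283 by limma camera with Benjamini-Hochberg, and adjusted p = 0.396 (miR-30) and adjusted p = 0.316 (miR-17-92) with an estimated correlation. The miR-23-27-24 clusters had 1 rise of 5, miR-27a-3p at 1.02 (2 adjusted over the list alone), with a median of 0.30; limma camera with Benjamini-Hochberg gave an adjusted p = 0.0161, and adjusted p = 0.647 with an estimated correlation. Those 5 medians kept their sign under each scaling tried. Fry called 2 lists.

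In the remaining lists miR-223-3p rose and miR-146a-5p fell among leukocyte miRNAs (2 and 2 adjusted over the list alone), miR-96-5p and miR-183-5p (at least 1.81-fold) rose and miR-31-5p and miR-203-3p (−0.77) fell among epithelial ones (3 and 2 adjusted over the list alone), both endothelial miR-126a arms fell, and miR-29b-3p rose by 1.00. The epithelial list had a median of 1.02, and its highest member, at 1.66, was not called by limma. Of the other 4 scalings miR-126a-3p was called under none (−0.67 to −0.26) and miR-126a-5p and miR-29b-3p under 1 each. Of the bile acid and nuclear receptor list 2 rose and 1 fell (2 and 2 adjusted over the list alone), and 0 of the stromal, erythroid, let-7, miR-15/16, miR-425-5p and Dlk1-Dio3 members were called by limma or adjusted over the list alone. The percentile of detected probes had a ratio of 0.980 between these groups. All 40 called miRNAs kept their sign under the other 4 scalings, and 4 of the 13 rises and 4 of the 27 falls were called under every one. With the percentile over all probes 5 were higher and 4 lower, without scaling 7 and 11, with total gene signal 8 and 11, and with slide row as a block 21 and 31; within row 2 it was 19 higher and 24 lower of 195 tested. The count was 24 without LIX1L KO BDL replicate 3 and 25 (5 higher, 20 lower) without sham replicate 2, and 3 were higher and 28 lower without sham replicate 1.

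Both ligated groups shared 6 miRNAs called higher than sham, among them miR-21a-5p, miR-223-3p, miR-29b-3p, miR-3473a and miR-3473b, and 25 called lower. Independent lists of these sizes would share 1.31 and 3.95, and simulated unchanged groups against the same sham arrays shared 0 and 0.01 on average. Unchanged groups give few calls that could be shared. Neither comparison therefore shows how much the shared sham arrays add to the overlap. The overlap was 6 with the percentile over all probes, 11 without scaling and 16 with spike-in scaling, against 31. Across miRNAs, which are not independent replicates, the changes of BDL and of LIX1L KO BDL against sham correlated with r = 0.77 (simulated 0.60), with a covariance of 0.25 (simulated 0.0363). The simulated miRNAs were drawn independently, while miRNAs on an array move together, so the distance from a simulated value is not a test. The 2 sham arrays give no parts of 2 arrays each, so part of the excess may come from them.

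The knockout change and the ligation change share the BDL arrays, so across miRNAs they run against each other even with no effect. Pearson's r was −0.53, against −0.45 (−0.61 to −0.25) in simulations of unchanged groups that share the BDL arrays, Spearman's rho −0.40 against −0.41, and the covariance −0.130 against −0.0243 (−0.0386 to −0.0128). Of all 219 miRNAs, 144 (65.8%) had a knockout change opposite in sign to the ligation change, where unchanged groups gave 64.7%. Of the correlations and the covariance, only the covariance lay outside its simulated range. The simulated miRNAs were drawn independently, while miRNAs on an array move together, so that range may be too narrow. The 3 BDL arrays give no parts of 2 arrays each, so part of that covariance may come from them.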

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

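The control probes were compared between groups only after the other results were seen. Signals of 3 control probes, out of 35 that the array design uses for quality control, were higher on every BDL array than on either sham array. No comparison above uses those 3. Of the 27 control probes with an unscaled signal above 100 on every array, 3 were higher on every BDL array than on either sham array and 14 lower, with ratios of 0.772 to 0.953. Chance gives 20% of probes for both directions together. The 3 higher ones share the name stem hur_6, so they may not be separate observations. Of the 14 lower, 5 were among the 8 spike-in probes. Their scaled signal is lowered by the scaling, with a percentile ratio of 1.21 against a spike-in ratio of 0.953. The ratio of the BDL mean to the sham mean of the scaled signal was 1.37 for hur_6_27, 1.25 for hur_6_28 and 1.23 for hur_6_29. The ratio of the LIX1L KO BDL mean to the sham mean was 0.991, 0.998 and 0.995 for the same probes. What these probes measure is not given in the sources used here, and no explanation was tested.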

How the results depend on the processing

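Added after the results were seen were slide row as a block, a fit to 1 slide row, spike-in scaling and the probe GC correction; the other alternatives were fixed before the data were examined. The 10 largest rises and 10 largest falls in BDL against sham kept their sign under every alternative that tested them, and for the named miRNAs of this comparison 1149 values kept direction and side of the threshold, 193 lost a call, 45 gained one and 35 changed sign. In LIX1L KO BDL against BDL these numbers were 1097, 68, 35 and 107, and in LIX1L KO BDL against sham 250 values kept both and 26 lost a call. Each of these named values whose sign changed was of a miRNA that had not passed the test in that comparison. With total gene signal 51 of all 54 calls in BDL against sham and 39 of all 40 in LIX1L KO BDL against sham kept their sign: miR-345-5p (−0.66 to 0.31), miR-378a-5p (−0.61 to 0.50) and miR-677-3p (−0.76 to 0.16) changed it in the former and miR-1839-3p (0.79 to −1.34) in the latter. The dimmest miRNAs are limited by signal over background, since values at the floor of 3.70 carry no difference. A slide or scan block was not run, as there were 1 slide and 1 scan, and the deposited table of all spots, identical to the scanner values, moved nothing. Except where stated, the cause of a difference was not tested.

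The calls in BDL against sham, 54, became 87 at an adjusted p under 0.1, 18 at an unadjusted p under 0.05 with at least 2-fold change, 10 with no filter, where more miRNAs were tested, and 102 with array weights. The 4 calls in LIX1L KO BDL against BDL became 23 at an adjusted p under 0.1 and 7 at an unadjusted p under 0.05 with at least 2-fold change. They became 42 with the percentile over all probes, 35 without scaling, 79 with spike-in scaling, 68 with array weights and 8 with a floor of 1. Quantile normalization, normexp and the probe GC correction each gave 1. Within slide row 1 the knockout side rests on a lone array, so only the size of the changes is given, above. By limma 0 were called with miRNAs detected on at least 1 array, with no filter, with miRNAs detected on all 8 arrays, with the gene detection flag, with only the 2 groups in the fit and with slide row as a block, with 16 to 50 at an unadjusted p under 0.05. The 40 calls in LIX1L KO BDL against sham became 15 at an unadjusted p under 0.05 with at least 2-fold change, 9 with the percentile over all probes, 18 without scaling, 19 with total gene signal and 2 with no filter. Leaving out 1 array at a time gave 28 to 84, 0 to 29 and 24 to 51 calls in the 3 comparisons; without 1 sham array the lone one was assumed to vary like the other groups.

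Of the lists, 3 were called in BDL against sham, 0 with an estimated correlation and 8 with no filter. In LIX1L KO BDL against BDL 2 were called, and 0 with an estimated correlation, with fry, with quantile normalization, with total gene signal, with miRNAs detected on all 8 arrays, with the gene detection flag and with a floor of 1. There was 1 list without scaling, with normexp, with the mean of all probes, with miRNAs detected on at least 1 array and with no filter. In LIX1L KO BDL against sham 5 were called, 0 with an estimated correlation, 2 with fry and 9 with no filter. Leaving out 1 array gave 3 to 4, 0 to 2 and 3 to 6 lists. The correlation of the ligation and knockout changes, −0.53, was −0.34 with normexp, −0.43 with miRNAs detected on all 8 arrays and −0.72 with slide row as a block, and −0.65 to −0.38 with 1 array left out. The overlap of 31 calls became 6 with the percentile over all probes, 11 without scaling, 17 with total gene signal, 2 with no filter and 16 with spike-in scaling.

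Samples of the same number did not deviate together: BDL and LIX1L KO BDL arrays with the same number in the description had correlations of 0.20, 0.19 and −0.27 of their deviations from the group means, and not every array correlated best with its own number, so the numbers were not read as a pairing. With the replicate block there were 40 calls in BDL against sham, 2 in LIX1L KO BDL against BDL and 29 in LIX1L KO BDL against sham, and the block called 1 list in LIX1L KO BDL against BDL.

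Signs that changed among the named miRNAs are given as log2 values. With the percentile over all probes the values were, in BDL against sham miR-29c-3p 0.23, miR-29a-3p 0.29, let-7d-5p 0.0023, let-7a-5p 0.14, miR-15b-5p 0.057, miR-16-5p 0.19 and miR-23b-3p 0.11, and in LIX1L KO BDL against BDL miR-22-3p −0.064, miR-29b-3p −0.11, miR-30d-5p −0.052, miR-30e-5p −0.11, miR-30c-5p −0.23, miR-98-5p −0.18, miR-223-3p −0.20, miR-126a-3p −0.32, miR-451a −0.13, miR-486a-5p −0.25, miR-19b-3p −0.11, miR-18a-5p −0.025, miR-322-5p −0.13, miR-15a-5p −0.25, miR-27b-3p −0.075, miR-23b-3p −0.090, miR-24-3p −0.072, miR-34a-5p −0.13, miR-425-5p −0.26 and miR-122-5p −0.23. With quantile normalization the values were, in BDL against sham miR-29a-3p 0.040, let-7d-5p 0.070, let-7a-5p 0.11 and miR-122-5p 0.14, and in LIX1L KO BDL against BDL miR-22-3p −0.0034 and miR-126a-3p −0.040. Without scaling the values were, in BDL against sham miR-29c-3p 0.18, miR-29a-3p 0.24, let-7a-5p 0.084, miR-15b-5p 0.0011, miR-16-5p 0.14 and miR-23b-3p 0.057, and in LIX1L KO BDL against BDL miR-22-3p −0.034, miR-29b-3p −0.078, miR-30d-5p −0.023, miR-30e-5p −0.084, miR-30c-5p −0.20, miR-98-5p −0.16, miR-223-3p −0.17, miR-126a-3p −0.29, miR-451a −0.10, miR-486a-5p −0.23, miR-19b-3p −0.085, miR-18a-5p −0.018, miR-322-5p −0.10, miR-15a-5p −0.22, miR-27b-3p −0.045, miR-23b-3p −0.060, miR-24-3p −0.042, miR-34a-5p −0.10, miR-425-5p −0.23 and miR-122-5p −0.20. With normexp background the values were, in BDL against sham miR-29a-3p 0.0089 and miR-425-5p −0.082, and in LIX1L KO BDL against BDL miR-378a-3p 0.043, miR-203-3p 0.14 and miR-126a-3p −0.033. With the mean of all probes the values were, in BDL against sham miR-29a-3p 0.012, and in LIX1L KO BDL against BDL miR-126a-3p −0.015 and miR-486a-5p −0.0094. With total gene signal the values were, in BDL against sham miR-214-3p −0.43 and miR-29a-3p 0.061, and in LIX1L KO BDL against BDL miR-345-5p −0.58, miR-30c-5p −0.012, miR-98-5p −0.011, miR-183-5p −0.16, miR-126a-3p −0.12, miR-486a-5p −0.038, miR-18a-5p −0.25, miR-15a-5p −0.049 and miR-425-5p −0.054. With array weights the values were, in LIX1L KO BDL against BDL miR-29a-3p 0.076, miR-451a −0.017 and miR-486a-5p −0.22. With slide row as a block the values were, in BDL against sham miR-425-5p −0.067, and in LIX1L KO BDL against BDL miR-29c-3p 0.091, miR-29a-3p 0.059, let-7e-5p −0.014, miR-16-5p 0.086 and miR-34a-5p −0.11. With spike-in scaling the values were, in BDL against sham miR-29c-3p 0.25, miR-29a-3p 0.31, let-7d-5p 0.016, let-7a-5p 0.15, miR-15b-5p 0.071, miR-16-5p 0.21 and miR-23b-3p 0.13, and in LIX1L KO BDL against BDL miR-22-3p −0.067, miR-29b-3p −0.11, miR-30d-5p −0.056, miR-30e-5p −0.12, miR-30c-5p −0.23, miR-98-5p −0.19, miR-223-3p −0.20, miR-126a-5p −0.038, miR-126a-3p −0.32, miR-451a −0.13, miR-486a-5p −0.27, miR-19b-3p −0.12, miR-18a-5p −0.098, miR-322-5p −0.14, miR-15a-5p −0.25, miR-27b-3p −0.078, miR-23b-3p −0.093, miR-24-3p −0.075, miR-34a-5p −0.14, miR-425-5p −0.27 and miR-122-5p −0.24. Within slide row 1 the values were, in LIX1L KO BDL against BDL miR-214-3p −0.017, miR-199a-3p −0.0048, miR-29c-3p 0.062, miR-29a-3p 0.029, let-7e-5p −0.043, miR-98-5p −0.011, miR-16-5p 0.057 and miR-34a-5p −0.14. After the probe GC correction the values were, in BDL against sham miR-425-5p −0.026, and in LIX1L KO BDL against BDL miR-126a-3p −0.021. With 1 array left out, the ranges in BDL against sham were −0.23 to 0.044 for miR-29c-3p, −0.21 to 0.14 for miR-29a-3p and −0.0051 to 0.56 for miR-322-5p. In LIX1L KO BDL against BDL they were −0.023 to 0.63 for miR-199a-3p, −0.073 to 0.068 for miR-29a-3p, −0.043 to 0.33 for miR-223-3p, −0.057 to 0.11 for miR-126a-3p, −0.12 to 0.42 for miR-486a-5p and −0.16 to 0.022 for miR-16-5p.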

Other observations

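All tests of this part were chosen after the results were seen, except the position of BDL replicate 4 between the groups, which was fixed before its value was computed.

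A deposited table of log2 values, whose name refers to quantile, held 137 miRNAs in the copy used here, 92 of them at the table's minimum of −3.32 on all 8 arrays and 40 above it on all 8. Of these, 32 were tested here. Across those 32 miRNAs the BDL minus sham difference in the deposited table correlated with the difference computed here at r = 0.824, with the same sign for 23 of 32 and for 6 of the 6 that were called. For LIX1L KO BDL minus BDL r was 0.794, with the same sign for 24 of 32. MiR-122-5p was at 0.13 for BDL minus sham in the deposited table and at −0.41 here, or 0.14 here under quantile normalization. Array by array, the deposited values of the 40 miRNAs correlated at 0.923 to 0.980 with quantile-normalized total gene signal.

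Between LIX1L KO BDL and BDL 4 miRNAs were lower, miR-721, miR-6898-5p, miR-146a-5p and miR-3963. The 10 splits of the 6 ligated arrays are too few for a share under 0.05; the real split gave 4 calls, the highest other split 0, and 1 split, the real one, gave as many. A slope on probe GC content as the whole cause is argued against by a corrected median of −0.95, with every one of the 4 still below 0 by more than 2 standard errors; the calls went from 4 to 1 (limma with Benjamini-Hochberg, adjusted p = 0.00881 for miR-721 and 0.0654 to 0.0660 for the others). Slide row as the whole cause cannot be decided. All BDL arrays lay in row 1 and both sham arrays in row 2, so only the knockout arrays set the row effect. With slide row as a block, the knockout side therefore rests on LIX1L KO BDL replicate 2 alone. The blocked median was −0.93. The changes went from −1.41, −1.18, −0.84 and −0.73 to −1.16, −1.14, −0.71 and −0.72 in the order above. The 4 calls ended as the standard errors grew 1.27 to 1.47 times, with the part of sizes and standard errors in this not separated. The LIX1L genotype named by the design stays open as an untested explanation, and the array measured no LIX1L.

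BDL replicate 4 correlated more closely with the knockout arrays (0.988 to 0.991) than with BDL replicates 1 and 3 (0.981 and 0.987). Over the 29 miRNAs called between LIX1L KO BDL and BDL without it, it lay at a median position of 0.34 (quartiles 0.16 and 0.45), with the knockout mean at 0 and the mean of the other BDL arrays at 1. That value lies between the ends of this scale, which does not show where a typical BDL array would fall. The 29 miRNAs were chosen because BDL replicates 1 and 3 differed from the knockout, which tends to place a left-out BDL array below 1. For some, such as miR-714 and miR-5121, replicate 4 and the knockout mean were both at the floor, so the position is 0. A mislabelled sample may be the cause and cannot be told apart from variation between mice. Slide row is argued against, since replicate 4 shared row 1 with both other BDL arrays and with only 1 of the 3 knockout arrays. A milder response of that mouse to ligation was not tested.

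The hepatocyte-abundant miRNAs were lower in BDL than in sham, with a mean of −0.56 over 8 miRNAs. A lower share of hepatocytes that raised every other cell type alike against this list is argued against by the endothelial list. It moved by −0.076 (SE 0.135) against the hepatocyte-abundant list, or −0.082 (SE 0.134) for miR-126a-3p alone (above the floor on all 8 arrays). The leukocyte list moved by 0.71 (SE 0.11). The stromal list moved by 0.63 (SE 0.50), the epithelial by 0.79 (SE 0.35) and the erythroid by −0.30 (SE 0.44). The endothelial list holds only 2 arms of miR-126a, and other cell types need not rise alike. A lower share of hepatocytes with an uneven rise of other cell types therefore stays open and was not tested. The array scaling may account for part of the fall: with spike-in scaling the median was −0.22, 7 of 8 members were below 0, 1 of them by more than 2 standard errors, and 1 was called, miR-378a-3p, so scaling and a true fall cannot be told apart for the other members. Bile duct ligation, which the design names, stays open as an untested explanation.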
